A study of Mus musculus with 48 samples.

How the data were processed

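RNA was measured by sequencing in the cerebral cortex of 48 mice that were 12 months old, 8 mice in each of 6 genotypes, with 4 females and 4 males per genotype. The genotypes were wild type, Msh3+/-, Msh3-/-, Q140 and Q140 combined with either Msh3 genotype. Q140 mice, all labelled heterozygous, carry a knock-in Htt allele with an expanded CAG repeat, the mouse counterpart of the Huntington disease mutation. The deposited counts are whole-number counts per Ensembl gene without normalization, and the deposited FPKM values divide those counts by a fixed gene length and by the library total. Dividing the counts by the FPKM gave back 1 length per gene to within 0.0251 bp in 16222 genes checked, so only the counts were analysed further. STAR 2.7.5c, SAMtools 1.10, HTSeq 0.12.3 and the builds GRCm38 and mm10 are named per the submitters' processing notes, without their roles or order. Per the labels' protocols, libraries were made with an Illumina TruSeq stranded kit. The annotation release and the strand setting used for counting are not stated, so whether genes that overlap on opposite strands were told apart in the counts is not known. The extraction protocol in the labels speaks of striatal tissue at 6 months, whereas every other label gives cortex at 12 months; the latter was used. Gene coordinates are those of GENCODE M21 on GRCm38.

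The counts table held 48795 genes, of which 14658 had 0 counts in every library. Symbols repeated over 134 names, and 27 symbols had been turned into dates, 24 of them among the genes tested, so genes were joined by Ensembl ID. Library totals ran from 37.7 to 68.3 mega (M) counts, with a median of 48.6 M. Expression is given as CPM, counts scaled by the normalized library total, with the SD over libraries, and log2 fold changes with their standard error. Counting error and the spread between mice both enter those errors.

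Genes were filtered with filterByExpr (minimum count 10, minimum total 15) by group, which left 19547 genes. Normalization was by TMM. One edgeR 4.0.16 quasi-likelihood model with 6 groups and an additive sex term was fitted to all 48 libraries (glmQLFit, legacy off, robust on), and each contrast was tested two-sided with glmQLFTest. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The 7 pairwise contrasts, the 2 interactions of Q140 with Msh3 genotype and the interaction of Q140 with sex in the 16 Q140 and wild-type libraries were chosen before the data were examined. So were the gene lists, the named-gene rule, the scores, the windows around Msh3 and Htt, and most of the alternatives. The 2 averaged contrasts, Q140 against no Q140 over the 3 Msh3 genotypes and Msh3-/- against Msh3+/+ over Q140 status, were added after the pairwise counts had been seen.

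Gene lists were 30 sets of 657 genes in all, of which 621 were tested. They covered mismatch repair; striatal, upper-layer, layer 5, layer 6, hippocampal and thalamic neurons; GABAergic interneurons; astrocytes and reactive astrocytes; oligodendrocytes and their precursors; microglia; endothelial, meningeal, choroid plexus and blood cells. The others were immediate early genes, activity-regulated peptides, glutamate receptors, potassium and sodium channels, clustered protocadherins, homeobox genes, cholesterol synthesis, nuclear and mitochondrially encoded respiratory genes, ribosomal proteins, heat shock, interferon and p53 genes. Each list was tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, one way. Member counts are given over all tested genes and adjusted over the list alone.

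For the score, the 16 Q140 and wild-type libraries were fitted alone, and the 100 genes of smallest p were taken because fewer than 50 genes passed. The score of a library is the mean of their centred log2 CPM, signed by the direction in Q140. Msh3 was left out. Groups that took no part in choosing the genes were compared by an exact permutation test within sex (4900 permutations, two-sided), and the difference of 2 shifts by 1e+05 random permutations. The double mutants were compared with Q140 by a score whose genes were chosen in the other sex. Calls near Msh3 and Htt, within 20 Mb, were compared with all other tested genes by Fisher's exact test, two-sided, Msh3 itself left out.

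Named genes were fixed by rule: Msh3 and Htt throughout; in each contrast the 10 rising and 10 falling genes of smallest adjusted p with a mean count of at least 20 in the higher group; and the 4 members of smallest p of each list called by camera. For Q140 against wild type, 2 members of every other list with a called member were added. Gene models without a symbol were counted but not named, except a cluster on chromosome 7, Gm2420 and AW495222, which were named after their values had been seen. Some genes that the rule names are not reported here.

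Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom with quality weights, no filter or a mean CPM of at least 1, no sex term, a replicate block, the plate column (6 levels), 2 surrogate variables (sva 3.50.0), name prefix as a random block, only the groups of the comparison, leaving out 2 wild-type mice of other name prefixes, an adjusted p under 0.1, and leaving out each library in turn. Leaving out 4 libraries high in choroid plexus, blood or pituitary genes (over 6 median absolute deviations above the median) was added after the data had been examined. Where alternatives are counted for a called gene, the adjusted p under 0.1 is among them and keeps the call by definition. Replicate numbers did not pair the libraries: 120 pairs of the same number and sex in different groups had a mean residual correlation of -0.00238. Libraries of the same name prefix in different groups (31 pairs) had a mean of 0.112, against -0.00315 for different prefixes (929 pairs). No library was a copy of another, the lowest chi-square per degree of freedom within groups being 7.97.

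The tests were checked on simulated negative binomial counts with the library totals, gene means and dispersions of these data and with genes independent of each other. At folds of 1.2, 1.5 and 2, edgeR recovered 44.6%, 75.3% and 82.9% of the changed genes, with 12 false calls among 150. A simulated change in ribosomal genes was called with a camera adjusted p of 2.79e-121 and 0 other lists. Because the simulated genes were independent, this check does not show how often camera calls lists by chance in these libraries. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.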

Results

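Gene expression was measured in the cerebral cortex of 48 mice aged 12 months. The design crossed the heterozygous Q140 Htt knock-in with the genotypes labelled Msh3+/- and Msh3-/-. Msh3 is a mismatch repair gene whose product drives somatic expansion of CAG repeats, and the comparisons ask how the cortical transcriptome of Q140 mice differs with Msh3 genotype. Each of the 6 genotypes had 8 libraries, 4 from females and 4 from males. Mean library totals, in mega (M) counts (± SD, n = 8), were 49.9 ± 8.64 M in wild type, 48.5 ± 5.94 in Msh3+/-, 50.5 ± 7.29 in Msh3-/-, 50.3 ± 3.98 in Q140, 47.8 ± 5.6 in Q140 with Msh3+/- and 49.8 ± 7.6 M in Q140 with Msh3-/-. Cortical genes were abundant in every library: the vesicular glutamate transporter gene Slc17a7 had a median of 1360 CPM, with a range from 1170 to 1500. Drd1 and Adora2a, genes of striatal projection neurons, had medians of 6.1 and 1.9 CPM.

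Msh3 (ENSMUSG00000014850, GRCm38 chromosome 13, 92211872 to 92355003) had 22.4 ± 1.16 CPM in wild-type libraries (SD, n = 8) and 21.8 ± 0.979 in Q140. The count was higher in the libraries labelled as mutants, at 60.1 ± 3.06 CPM in Msh3+/- and 99.2 ± 8.15 CPM in Msh3-/-. With Q140 the corresponding levels were 57.9 ± 3.01 and 95.3 ± 8.03 CPM. The log2 fold changes were 1.43 ± 0.045 for Msh3+/- against wild type (edgeR adjusted p = 2.44e-31) and 2.15 ± 0.045 for Msh3-/- (adjusted p = 1.62e-40). The deleted part of the gene and the parts of it that were counted are not stated, so the count per gene does not measure how much functional transcript was lost. Single libraries ranged from 20.5 to 23.5 CPM in wild type, from 55.3 to 64.7 in Msh3+/- and from 84.2 to 108 in Msh3-/-. Htt (GRCm38 chromosome 5, 34761740 to 34912534) had 245 ± 11 CPM in wild type and 242 ± 12.1 in Q140, a log2 fold change of -0.02 ± 0.036 (edgeR adjusted p = 0.915), and was not called in any comparison.

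**Figure D1:**
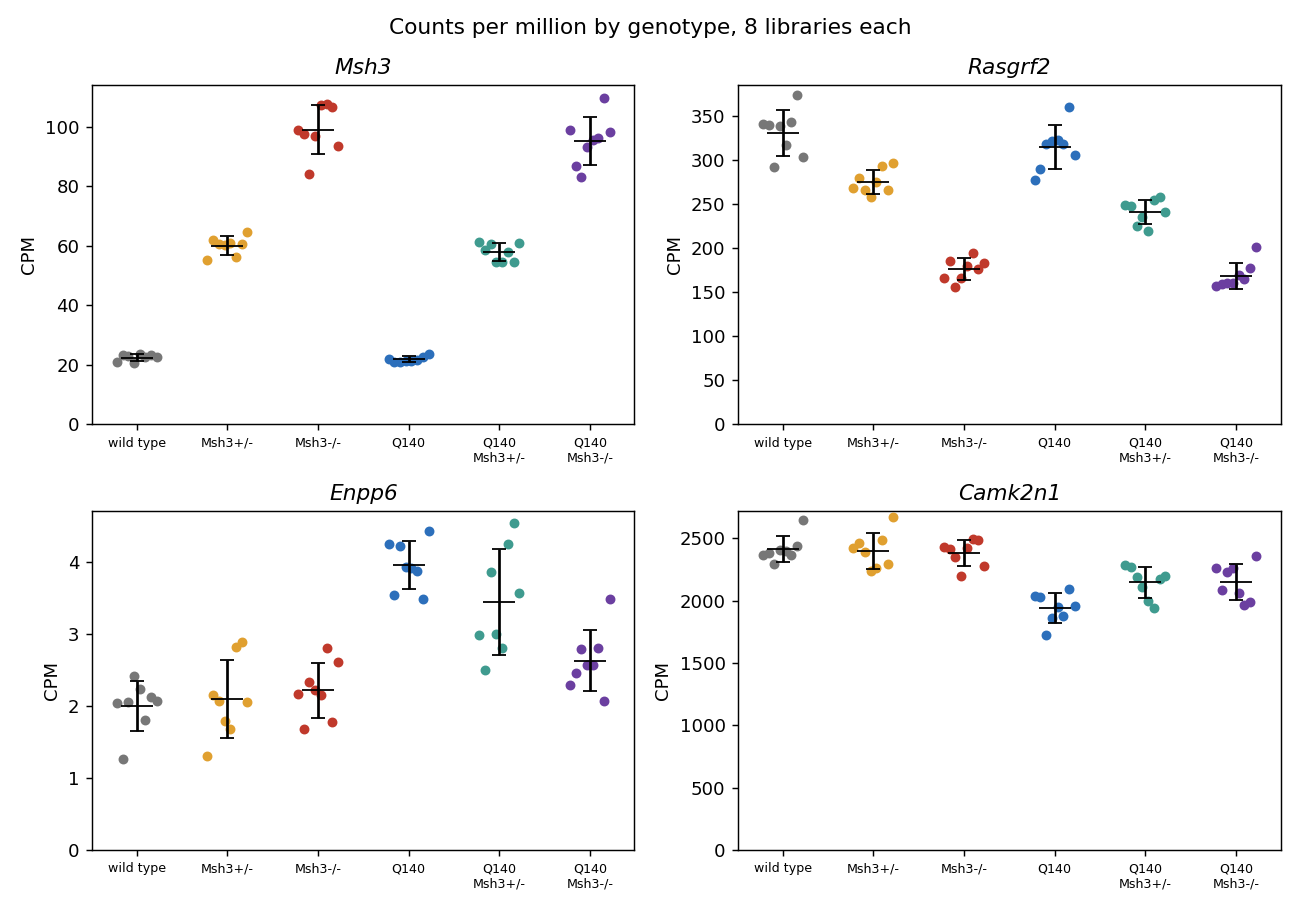
CPM of Msh3, Rasgrf2, Enpp6 and Camk2n1 in the 6 genotypes, where each point is 1 library and the bar is the group mean ± SD of 8 libraries. Msh3 went from 22.4 CPM in wild type to 99.2 in Msh3-/-, and Rasgrf2 from 331 to 176, whereas Enpp6 went from 2.0 in wild type to 3.96 in Q140 and Camk2n1 from 2410 to 1940.

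Q140 mice differed from wild type in 20 genes. Camk2n1, which encodes an inhibitor of the kinase CaMKII, fell from 2410 to 1940 CPM (log2 fold change -0.31 ± 0.039, n = 8 per group, edgeR adjusted p = 6.9e-07). Camk2a, the alpha subunit of that kinase, went from 5250 to 4710 CPM (-0.15 ± 0.033). The astrocyte genes Slc1a2, the main glutamate transporter, and Glul, glutamine synthetase, fell by 0.21 and 0.17 on the log2 scale, with Slc4a4, a sodium bicarbonate cotransporter, at -0.18 ± 0.04. Ddit4l, an inhibitor of mTOR signalling, fell from 52.2 to 34.9 CPM (adjusted p = 0.000278) and the neuropeptide gene Cartpt from 5.46 to 3.91 CPM (adjusted p = 0.0419). Among genes that rose, Enpp6, a marker of newly forming oligodendrocytes, went from 2.0 to 3.96 CPM (log2 fold change 0.97 ± 0.12, adjusted p = 6.82e-07). Zfp488, a regulator of oligodendrocyte differentiation, rose by 0.49 ± 0.091 and Anln, which encodes anillin, by 0.45 ± 0.096. Tmc3 went from 0.512 to 1.35 CPM (adjusted p = 7.34e-07).

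In all, edgeR called 20 of 19547 genes in Q140 against wild type, 8 higher and 12 lower, and 1720 genes had an unadjusted p under 0.05. Of these calls, 4 lay within 20 Mb of Htt: Abhd1 (log2 fold change 1.01 ± 0.096, chromosome 5, 30950066 to 30955091), Cgref1 (0.47 ± 0.076), Atraid (-0.21 ± 0.04) and the gene model Gm2420 (4.41 ± 0.515), the last named after its value was seen. Leaving out 1 library gave from 13 to 23 calls, with 13 when wild-type F4, wild-type M2 or Q140 M2 was left out. Some calls leaned on single libraries: over the 16 fits without 1 library, Camk2a was called in 7, Slc4a4 in 6, Cartpt in 5 and Anln in 9. Prl, the pituitary hormone prolactin, was also called lower (-4.38 ± 0.91), but wild-type M2 carried pituitary transcripts, and without it the adjusted p was 0.438. The H2 class genes H2-Bl and H2-T-ps were called lower (-0.82 and -0.70), and they belong to a family whose reads align to several members. With the 4 libraries high in choroid plexus or pituitary genes left out, 8 genes were called, and with a term for plate column 11. Both alternatives ended the calls of Slc1a2, Camk2a, Slc4a4 and Cartpt. Plate columns held Q140 and wild-type libraries in unequal shares, so a plate effect cannot be fully separated from Q140.

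Gene lists moved by small amounts in Q140 against wild type. Astrocyte genes had a median log2 fold change of -0.084, with 17 of 20 members below 0 and 2 called lower (Slc1a2 and Slc4a4), also 2 when adjusted over the list alone; Clu, the apolipoprotein clusterin, had -0.12 ± 0.047. Genes of upper-layer glutamatergic neurons had a median of -0.075 over 17 members, of which 0 were called and 1 fell when adjusted over the list alone; Lamp5 had -0.22 ± 0.064 and Stard8 -0.14 ± 0.05. Nuclear-encoded oxidative phosphorylation genes had a median of 0.044 with 34 of 40 members above 0, and ribosomal protein genes 0.064 with 41 of 49 above 0, neither with a called member. The 13 mitochondrially encoded genes all lay below 0, with a median of -0.17. Immediate early genes, which neurons switch on with activity, had a median of 0.20, with 18 of 20 above 0 and none called. Camera at the preset correlation called these 6 lists with adjusted p = 1.02e-07, 0.00122, 3.34e-05, 0.000127, 0.000287 and 0.00122. With an estimated correlation their adjusted p were 0.195, 0.195, 0.507, 0.507, 0.507 and 0.631, and none was called.

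Camera called 5 other lists in Q140 against wild type. Cholesterol synthesis genes had a median of 0.056 (26 genes, adjusted p = 0.00122, 0.528 with an estimated correlation), and 1 rose when adjusted over the list alone. Endothelial and mural genes had -0.091 (22 genes, adjusted p = 0.00217, 0.507 with an estimated correlation). Oligodendrocyte and myelin genes had -0.053 (24 genes, adjusted p = 0.00903, 0.72 with an estimated correlation), with 2 lower when adjusted over the list alone; Tspan2 had -0.28 ± 0.066. Glutamate receptor and postsynaptic genes had -0.032 (26 genes, adjusted p = 0.00771, 0.507 with an estimated correlation), 1 of them, Camk2a, called lower and 2 when adjusted over the list alone. Potassium and sodium channel genes had -0.056 (25 genes, adjusted p = 0.0117, 0.507 with an estimated correlation), with 2 lower when adjusted over the list alone; Kcna1 had -0.23 ± 0.073. Fry, run over the same 30 lists, called 0 of them.

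The other 19 lists were not called by camera in Q140 against wild type. For neurons these were the lists of striatal projection neurons (median 0.023, but a test direction downward, adjusted p = 0.7), layer 5 (0.030, adjusted p = 0.53), layer 6 (0.069, adjusted p = 0.394), GABAergic interneurons (0.022, adjusted p = 0.283), hippocampal (adjusted p = 0.717) and thalamic neurons (adjusted p = 0.283). For other cells they were oligodendrocyte precursors (-0.063, adjusted p = 0.16, with Enpp6 the only member called), microglia (-0.017, adjusted p = 0.353), meningeal cells (-0.062, adjusted p = 0.353), choroid plexus (-0.17, adjusted p = 0.402), blood (1.57, adjusted p = 0.0613) and reactive astrocytes (-0.077, adjusted p = 0.197). Mismatch repair (adjusted p = 0.646), activity-regulated peptides (-0.094, adjusted p = 0.283, Cartpt called lower), clustered protocadherins (adjusted p = 0.646), homeobox genes (adjusted p = 0.353), heat shock (0.031, adjusted p = 0.207), interferon response (-0.028, adjusted p = 0.402) and p53 genes (adjusted p = 0.717) completed the set.

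**Figure D2:**
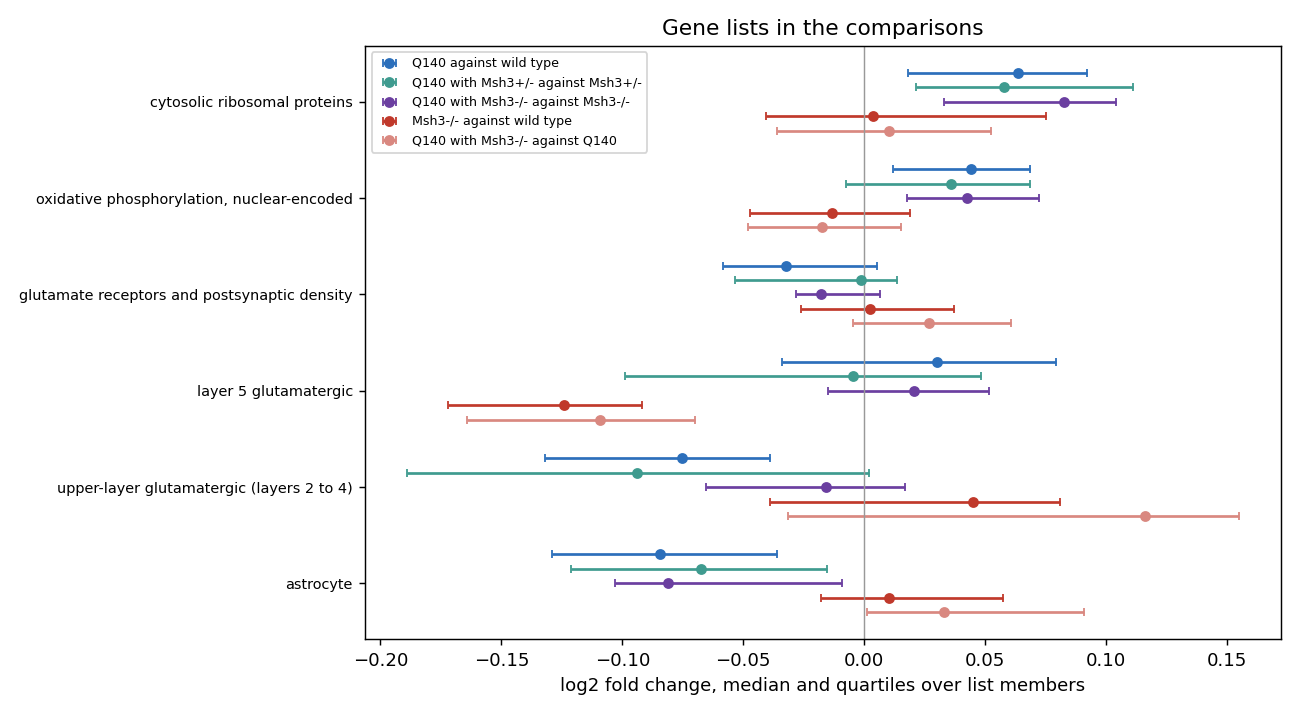
Median log2 fold change of 6 gene lists in 5 comparisons, with bars from the lower to the upper quartile of the members. Astrocyte genes lay at -0.084 and ribosomal protein genes at 0.064 in Q140 against wild type, and layer 5 genes at -0.12 in Msh3-/- against wild type.

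With Msh3+/- in both groups, Q140 again came with higher Abhd1 (1.35 ± 0.099), Tmc3 (1.36 ± 0.185), Enpp6 (0.73 ± 0.124), Cgref1 (0.49) and Anln (0.48), and with lower Ddit4l (-0.45 ± 0.09), Slc1a2 (-0.19 ± 0.041) and Atraid (-0.30 ± 0.04). Mrpl33, a mitochondrial ribosomal protein gene near Htt, rose by 0.37 ± 0.061. EdgeR called 10 genes, 7 higher and 3 lower, with 1518 at an unadjusted p under 0.05. Over 14 alternatives Slc1a2 was called in 9, Anln in 10, and Ddit4l and Enpp6 in 13, and over 16 fits without 1 library Slc1a2 was called in 4, Anln in 6 and Ddit4l in 9. Name prefix as a random block was among the alternatives that ended the call of Slc1a2. With Msh3-/- in both groups, 4 genes were called: Abhd1 (1.16 ± 0.094, edgeR adjusted p = 1.01e-12), Tmc3 (1.30 ± 0.22), Gm2420 (3.25) and Atraid (-0.25 ± 0.04), with 1323 genes at an unadjusted p under 0.05. All 20 genes called in Q140 against wild type had the same direction on Msh3+/-, where 9 of them were called, and 18 had it on Msh3-/-, where 4 were called. Of the 16 genes outside 20 Mb of Htt, 16 had the same direction on Msh3+/- and 5 were called there, and on Msh3-/- 14 had it and 1, Tmc3, was called, a call that ended with only the groups of the comparison in the fit. No library was shared between these comparisons. Chance expected 0.00471 and 0.00184 shared calls with all genes, values that do not allow for linkage to Htt. The median size of the 20 effects, signed by their direction in Q140 against wild type, was 0.488 there, 0.337 on Msh3+/- and 0.158 on Msh3-/- (0.292 and 0.148 for the 16 outside the window). The first value is inflated because it chose the genes.

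Among lists, astrocyte genes had a median of -0.067 for Q140 on Msh3+/- (1 called lower, Slc1a2, and 3 when adjusted over the list alone) and -0.081 on Msh3-/- (0 called, 2 when adjusted over the list alone). Camera called both (adjusted p = 1.42e-05 and 0.000218), but not with an estimated correlation (adjusted p = 0.26 and 0.834). Ribosomal protein genes had medians of 0.058 and 0.083 (camera adjusted p = 5.08e-07 and 5.94e-06, with an estimated correlation 0.347 and 0.834). On Msh3+/-, upper-layer genes had a median of -0.094, with 0 called and 5 lower when adjusted over the list alone (camera adjusted p = 0.000151, 0.142 with an estimated correlation). In the same comparison the choroid plexus list had a median of -1.86, with 9 of 9 genes lower when adjusted over the list alone, and the meningeal list -0.37 (adjusted p = 0.26 and 0.347 with an estimated correlation). The Msh3+/- library M2 held a choroid plexus score of 3.39 against a median of -0.822 over all libraries.

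Averaging Q140 against no Q140 over the 3 Msh3 genotypes, 24 libraries against 24, resolved smaller effects. Slc1a2 (-0.18 ± 0.024, edgeR adjusted p = 7.86e-07), Glul (-0.17 ± 0.023, adjusted p = 2.59e-06), Gja1, which encodes the gap junction protein connexin 43 (-0.14 ± 0.027), and Slc4a4 (-0.13 ± 0.023) were lower in Q140 carriers. Of the 20 astrocyte genes, 7 fell and 9 when adjusted over the list alone, with a list median of -0.078. Camk2n1 (-0.21 ± 0.023, adjusted p = 6.46e-09), Camk2a (-0.12 ± 0.019), Grin2a, an NMDA receptor subunit (-0.12 ± 0.028), and Penk, the enkephalin precursor (-0.22 ± 0.043), were also lower. Of 17 upper-layer genes, 3 fell (Stard8 at -0.17 ± 0.029, Lamp5 at -0.17 ± 0.037 and Rasgrf2 at -0.11 ± 0.025) and 4 when adjusted over the list alone. Of 49 ribosomal protein genes, 3 rose (Rpl32 by 0.11 and Rplp1 by 0.10 among them) and 18 when adjusted over the list alone, and of 40 oxidative phosphorylation genes 1 rose (Ndufs7, by 0.10) and 11 when adjusted over the list alone. Measured against genes of like length and expression, 83% of the median shift of ribosomal protein genes and 46.8% of that of oxidative phosphorylation genes was left. Enpp6 (0.64 ± 0.072), Anln (0.35 ± 0.056), Sstr1, a somatostatin receptor (0.21 ± 0.04), and Acot7, an acyl-CoA thioesterase (0.12 ± 0.021), were higher.

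In this averaged contrast edgeR called 288 genes, 139 higher and 149 lower, with 2944 at an unadjusted p under 0.05. Camera called 14 lists, none of which was called with an estimated correlation. For astrocytes and upper layers the adjusted p was 0.0613 with an estimated correlation and 0.00347 by fry, and for ribosomal proteins 0.294 and 0.0282; fry called these 3 lists. Activity-regulated peptide genes had a median of -0.028, with 2 of 17 lower, Penk and Cartpt, and cholesterol synthesis genes 0.038, with 0 called and 4 higher when adjusted over the list alone (adjusted p = 0.515 with an estimated correlation for both). The meningeal list (median -0.19), the choroid plexus list (-0.74) and the blood list (0.81) moved with Q140 in the same contrast, with adjusted p of 0.515 with an estimated correlation. Leaving out 1 library gave from 201 to 475 calls, with 475 without Msh3-/- F3 and 454 without Q140 with Msh3+/- F1. The plate column term gave 102 calls and ended those of Rpl32, Rplp1, Ndufs7, Grin2a and Rasgrf2. Q140 carriers were unevenly spread over the plate columns, so a plate effect cannot be fully separated from Q140 here either.

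In libraries labelled Msh3-/- against wild type, Rasgrf2, a Ras exchange factor (chromosome 13, 91880400 to 92131656), fell from 331 to 176 CPM (log2 fold change -0.92 ± 0.044, n = 8 per group, edgeR adjusted p = 9.18e-23). Cmya5, which encodes myospryn, fell from 16.6 to 7.87 CPM (-1.09 ± 0.073), F2rl2, a thrombin receptor gene, from 2.71 to 1.2 CPM (-1.14 ± 0.164) and Fam169a from 81 to 64.5 CPM (-0.33 ± 0.033). Bhmt2, a homocysteine methyltransferase (-1.12 ± 0.188), Ankrd34b (-0.39 ± 0.049), the ceramide transfer gene Col4a3bp (-0.16 ± 0.033) and the versican gene Vcan (-0.24 ± 0.052) also fell. F2r, another thrombin receptor, rose from 3.72 to 6.23 CPM (0.73 ± 0.1) and Dmgdh, dimethylglycine dehydrogenase, from 0.554 to 1.26 CPM (1.18 ± 0.213). The model AW495222, named after its value was seen, fell by 1.11 and lies inside Dmgdh. Whether their reads were separated by strand is not known. Away from chromosome 13, Insm1, a zinc finger transcription factor, rose by 0.55 ± 0.104 and Tesk2 by 0.28, while Tbl1x and Wdr44 fell by 0.16 and 0.18. Over 16 fits without 1 library, Vcan was called in 6, Tesk2 in 8, Tbl1x in 12 and Col4a3bp in 14, and over 14 alternatives Tesk2 and Tbl1x were called in 9, Vcan and Col4a3bp in 11 and Insm1 in 13.

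EdgeR called 22 genes in Msh3-/- against wild type, 6 higher and 16 lower, with 2119 at an unadjusted p under 0.05. In Msh3+/- against wild type it called 6, 1 higher and 5 lower, with 969 at an unadjusted p under 0.05: besides Msh3 these were Rasgrf2 (-0.27 ± 0.044), Cmya5 (-0.33 ± 0.068) and 3 gene models of chromosome 7. The call of Cmya5 held in 4 of 16 fits without 1 library and under 7 of 14 alternatives, and it ended with name prefix as a random block. A cluster of such models there (36710174 to 36734558), singled out after its values were seen, was lower in every Msh3 mutant group: E230020A03Rik had 2.78 CPM in wild type and 1.8 in Q140 and fell by 2.02 in Msh3+/- and 2.34 in Msh3-/-, and Gm37827 fell by 2.35 and 2.62. Prl was called in Msh3-/- against wild type (-5.28 ± 1.018) but not without wild-type M2 (adjusted p = 0.331). With only the libraries of the comparison in the fit, 13 genes were called for Msh3-/- and 2 for Msh3+/-. Without the libraries high in choroid plexus or pituitary genes, 2 were called for Msh3+/-.

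In Q140 mice, Msh3-/- changed most of the same neighbours of Msh3. Rasgrf2 fell from 315 to 169 CPM (-0.90 ± 0.044, edgeR adjusted p = 2.18e-22), Cmya5 by 1.09 ± 0.074 and Fam169a by 0.34 ± 0.033, and F2r rose by 0.67 ± 0.098. Other changes touched genes that differed between Q140 and wild type: Enpp6 fell from 3.96 to 2.63 CPM (-0.59 ± 0.113, adjusted p = 0.00585), Zfp488 from 2.98 to 2.16 CPM (-0.46 ± 0.09) and Tmc3 from 1.35 to 0.771 CPM (-0.80 ± 0.156), and Cartpt, which lies within 20 Mb of Msh3 (chromosome 13, 99898489 to 99901091), rose from 3.91 to 5.51 CPM (0.50 ± 0.108, adjusted p = 0.0301). Crhbp, which encodes a protein that binds corticotropin-releasing hormone (chromosome 13, 95431371), rose from 14.3 to 18.3 CPM (0.35 ± 0.075), and Plxnd1, a semaphorin receptor, and Ramp1, a receptor activity-modifying protein, rose by 0.19 and 0.20. With only the groups of the comparison in the fit, Zfp488, Tmc3, Plxnd1 and Ramp1 were not called. Leaving out 1 library kept the call of Cartpt in 7 of 16 fits, of Crhbp in 8, of Plxnd1 in 7 and of Ramp1 in 4.

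EdgeR called 20 genes in Q140 with Msh3-/- against Q140, 7 higher and 13 lower, with 1340 at an unadjusted p under 0.05. Of these, 12 were called in the same direction in Msh3-/- against wild type, where chance expected 0.0128 and no library was shared. They were Msh3, its chromosome 13 neighbours Rasgrf2, Cmya5, Fam169a, Ankrd34b, F2r, F2rl2, Bhmt2, Col4a3bp and AW495222, and the chromosome 7 models E230020A03Rik and Gm37827. Both comparisons contrast the same Msh3 allele, and the chance value does not allow for linkage to it. Leaving out 1 library gave from 13 to 24 calls, with 13 without Q140 with Msh3-/- M4. In Q140 with Msh3+/- against Q140, 6 genes were called, with 1216 at an unadjusted p under 0.05: Msh3 rose, and Rasgrf2 (-0.38), Cmya5 (-0.47), Fam169a (-0.19) and the chromosome 7 models Gm37827 and E230020A03Rik fell. Of these, 5 were also called in the same direction in Msh3+/- against wild type.

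In Msh3+/- against wild type, choroid plexus genes had a median of 1.33, with 0 called and 8 of 9 higher when adjusted over the list alone (camera adjusted p = 0.00107, 0.691 with an estimated correlation), and Msh3+/- M2 stood apart in them. In Msh3-/- against wild type, blood genes had a median of 2.89, with 0 called and 4 of 5 higher when adjusted over the list alone (camera adjusted p = 0.0174, 0.694 with an estimated correlation), and meningeal genes -0.20 (0.0431, adjusted p = 0.898 with an estimated correlation). In Q140 with Msh3-/- against Q140, potassium and sodium channel genes had a median of 0.044, with 0 called and 3 higher when adjusted over the list alone (camera adjusted p = 0.00477, 0.721 with an estimated correlation), Kcnip2 at 0.15 ± 0.044 and Kcnc1 at 0.13 ± 0.039 among them. Astrocyte genes had 0.033 there (camera adjusted p = 0.044, 0.947 with an estimated correlation), with Slc4a4 at 0.12 ± 0.04, and meningeal genes -0.27 (camera adjusted p = 0.00477, 0.947 with an estimated correlation).

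Calls gathered around both engineered loci. Within 20 Mb of Msh3, edgeR called 11 of 211 tested genes in Msh3-/- against wild type and 10 of 19262 elsewhere (odds ratio 106, 95% confidence interval 40.2 to 279, Fisher's exact p = 5.97e-17). With Q140 in both groups the numbers were 11 inside and 8 outside (odds ratio 132, exact p = 1.3e-17), and for Msh3+/- 2 and 3 (odds ratio 61.3, exact p = 0.00114). Within 20 Mb of Htt, 4 of 334 genes were called in Q140 against wild type and 16 of 19139 elsewhere (odds ratio 14.5, 95% confidence interval 3.5 to 45.2, exact p = 0.000331). On Msh3+/- the calls were 5 inside and 5 outside (odds ratio 58, exact p = 3.38e-07), and on Msh3-/- 3 and 1 (odds ratio 172, exact p = 1.98e-05).

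**Figure D3:**
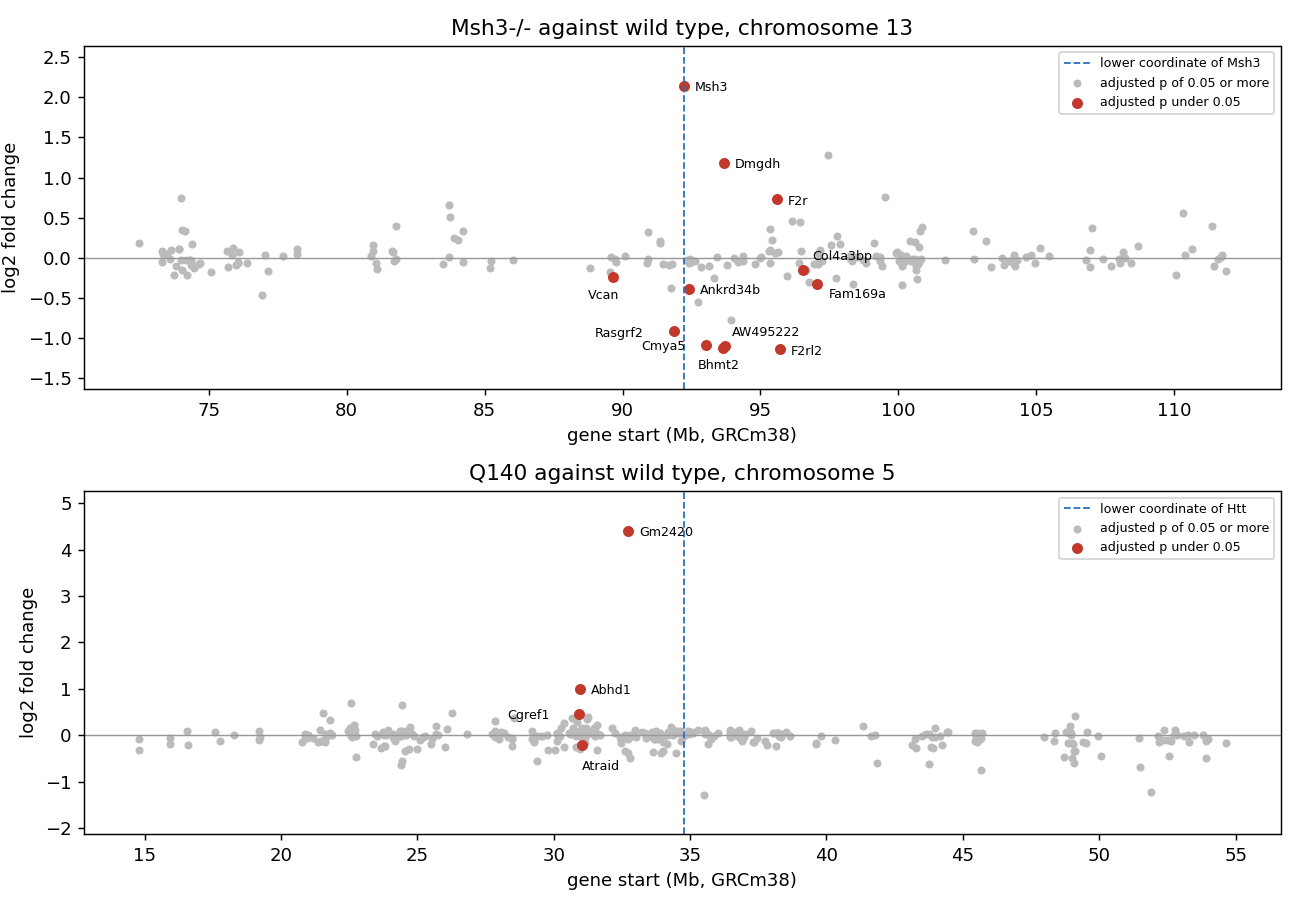
Log2 fold change of tested genes by their start along chromosome 13 around Msh3 (Msh3-/- against wild type) and along chromosome 5 around Htt (Q140 against wild type), with called genes in red and the dashed line at the lower coordinate of Msh3 or Htt. Called genes include Rasgrf2 at -0.92 and F2r at 0.73 near Msh3, and Abhd1 at 1.01 and Atraid at -0.21 near Htt.

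Averaged over Q140 status, 16 libraries labelled Msh3-/- against 16 without a Msh3 mutation, the layer 5 list was lower, and single genes passed the test. Gabrd, a delta subunit of the GABA-A receptor, rose by 0.15 ± 0.031 (edgeR adjusted p = 0.0113) and Gabra5, its alpha 5 subunit, fell by 0.23 ± 0.047 (adjusted p = 0.0113), though its call ended without the sex term and with 2 surrogate variables. Insm1 (0.40 ± 0.072), Plk5 (0.38 ± 0.071) and, within 20 Mb of Msh3, Crhbp (0.29 ± 0.053) rose. The call of Plk5 also ended with 2 surrogate variables. Tmc3 fell by 0.77 ± 0.144. Nnt, the mitochondrial transhydrogenase gene of distal chromosome 13 (119335448 to 119408997), rose by 0.51 ± 0.091, from 26.3 CPM in wild type to 36.7 in Msh3-/-. Nnt lies on the same chromosome as Msh3, beyond the 20 Mb window, and its linkage to the Msh3 allele was not tested. Layer 5 genes had a median of -0.12, with 15 of 16 below 0, 0 called and 4 lower when adjusted over the list alone; Ldb2 had -0.27 ± 0.072 (adjusted p = 0.0854) and Fezf2, a determinant of layer 5 identity, -0.18 ± 0.052 (adjusted p = 0.098). Camera called this list (adjusted p = 1.31e-06) and kept the call with an estimated correlation (adjusted p = 0.0306), as did fry (adjusted p = 0.000933).

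The contrast called 42 genes by edgeR, 18 higher and 24 lower, with 2921 at an unadjusted p under 0.05. Mismatch repair genes were the other list called with an estimated correlation (adjusted p = 2.55e-07), by Msh3 alone: 1 of 18 rose, with a list median of 0.00066. The mismatch repair list was likewise the only list that kept its call with an estimated correlation in each pairwise comparison of Msh3 genotypes. The layer 5 medians were -0.12 in Msh3-/- against wild type (camera adjusted p = 0.000481, 0.213 with an estimated correlation), -0.11 in Q140 with Msh3-/- against Q140 (1.15e-05, 0.0614) and -0.068 in Msh3+/- against wild type (0.0243, 0.691). The upper-layer list had a median of 0.049 but a test direction downward (camera adjusted p = 0.284); it holds Rasgrf2, and it was not tested without that gene. Leaving out 1 library gave from 28 to 109 calls, with 76 without wild-type F2, 90 without Q140 M1, 97 without Q140 with Msh3-/- F1 and 109 without Q140 with Msh3-/- M2.

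Whether the Q140 effect differed with Msh3 genotype was tested gene by gene. Enpp6 had the log2 fold change 0.97 ± 0.12 for Q140 on wild-type Msh3 and 0.23 ± 0.127 on Msh3-/-, a difference of -0.74 ± 0.176 (edgeR adjusted p = 0.772). For Zfp488 the difference was -0.52 ± 0.133 (adjusted p = 0.949), for Camk2n1 0.17 ± 0.056 (adjusted p = 1) and for Ddit4l 0.32 ± 0.127 (adjusted p = 1), and for Tmc3 it was -0.06 ± 0.308 (adjusted p = 1). EdgeR called 0 genes for the interaction with Msh3+/- and 0 with Msh3-/-, with 646 and 626 at an unadjusted p under 0.05. DESeq2 called 0 and 0 (643 and 562 unadjusted), as did limma-voom (686 and 617). The interaction of Q140 with sex also had 0 calls by edgeR, DESeq2 and limma-voom, with 838, 842 and 871 at an unadjusted p under 0.05.

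Enpp6, Tmc3 and Zfp488 rose and Cartpt fell in Q140 against wild type, and all 4 were called the opposite way in Q140 with Msh3-/- against Q140. Both comparisons use the same Q140 libraries, which favours opposite calls. Independent comparisons would give 0.00962 such genes, a value that leaves this sharing out. Random regrouping of the libraries gave at most 0 in 100 draws, but random groups call few genes of any kind, so that value does not weigh the sharing either. When the Q140 libraries were divided between the comparisons, 1 gene (Tmc3) and 0 genes were called the opposite way. Tmc3 was also lower without Q140, at 0.512 CPM in wild type and 0.323 in Msh3-/-. Its Q140 effect was 1.36 ± 0.172 on wild-type Msh3 and 1.30 ± 0.22 on Msh3-/-. The opposite call of Tmc3 thus does not show a weaker Q140 effect on Msh3-/-.

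A score over the 100 genes of smallest p in Q140 against wild type, 33 higher and 67 lower, summarised the response per library. The Q140 and wild-type groups, which chose the genes, scored 0.23 ± 0.036 and -0.171 ± 0.0666 (SD, n = 8). Groups that played no part in the choice also differed: Q140 with Msh3+/- scored 0.0825 ± 0.0739 against -0.0997 ± 0.0467 in Msh3+/-, a shift of 0.182 (exact permutation p = 0.000816, two-sided). Q140 with Msh3-/- scored 0.0577 ± 0.0522 against -0.0994 ± 0.0471 in Msh3-/-, a shift of 0.157 (exact permutation p = 0.000816). The shifts differed by 0.025 (permutation p = 0.524). With 500 genes they were 0.0976 and 0.094 (exact permutation p = 0.00367 and 0.000408), and without genes near Htt or Msh3 0.139 and 0.115.

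With genes chosen in 1 sex and scored in the other, Q140 scored 0.116 ± 0.0402 and wild type -0.0657 ± 0.0656, a difference of 0.181 (exact permutation p = 0.000408, the smallest that 4900 permutations give). Q140 with Msh3+/- scored 0.116 ± 0.0483, a difference from Q140 of 0.000363 (exact permutation p = 0.988). That mean joined opposite signs, -0.0378 in females (exact permutation p = 0.343) and 0.0386 in males (exact permutation p = 0.0286, the smallest that 70 permutations give); the difference between the sexes was not tested. Q140 with Msh3-/- scored 0.0574 ± 0.0471, a difference of -0.0583 (exact permutation p = 0.0216), which was -0.0595 in females and -0.057 in males (exact permutation p = 0.0571 and 0.143, n = 4 per group and sex). The latter difference missed the threshold with 500 genes (-0.0193, permutation p = 0.313) or with a median in place of the mean (-0.0344, permutation p = 0.109). In libraries without Q140 the score with genes chosen in the other sex was -0.0906 ± 0.0455 in Msh3-/- and -0.0657 ± 0.0656 in wild type. Whether the lower score with Msh3-/- differed between mice with and without Q140 was not tested. The comparison with Q140 thus does not show a weaker Q140 effect on Msh3-/-.

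**Figure D4:**
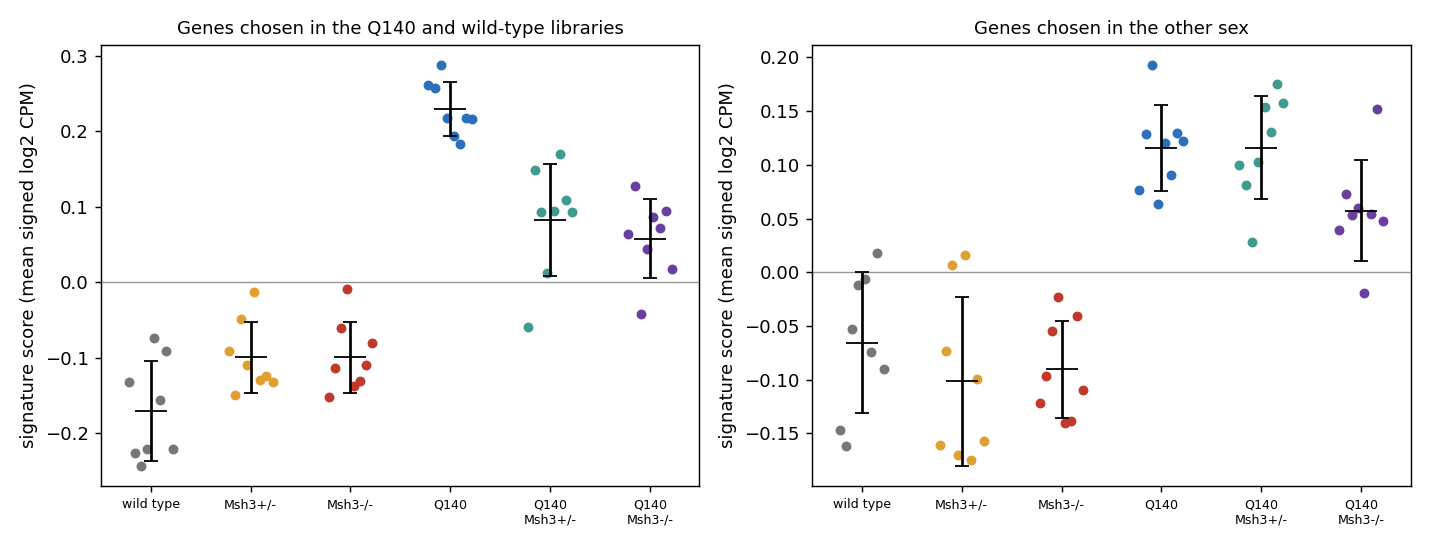
Q140 score per library (mean signed centred log2 CPM over 100 genes) in the 6 genotypes, with points for libraries and bars for the mean ± SD of 8; on the left the genes were chosen in all Q140 and wild-type libraries, on the right in the other sex. On the right, Q140 averaged 0.116, Q140 with Msh3+/- 0.116 and Q140 with Msh3-/- 0.0574.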

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

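Of the tests below, 5 were chosen only after the result was seen: the odds ratio near Htt, the share of calls on other chromosomes, the median size of the calls with the striatal term, and the counts of Y-linked and of escaping X-linked genes. Among 223 groups of values examined for a single library that stood apart, 7 had one, where 11.2 would be expected by chance.

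Genes within 20 Mb of Msh3, such as Rasgrf2, Cmya5 and F2r, were called in Msh3-/- against wild type with an odds ratio of 106 against other genes. Sequence of another strain carried along with the engineered allele may account for these calls, though an effect of the altered Msh3 locus on its neighbours was not tested and stays open. Near Htt the odds ratio in Q140 against wild type was 14.5, so linked sequence may account for Abhd1, Cgref1, Atraid and Gm2420. These made up 20% of the calls, between the bounds set beforehand for linkage as the main or as a minor source, so that share leaves the matter open for the comparison as a whole. Linkage to Htt cannot account for the 75% of calls that lay on other chromosomes, Camk2n1, Enpp6 and Slc1a2 among them.

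For the calls of Q140 against wild type, a differing amount of striatal tissue in the dissections was tested by adding the mean of Scn4b, Pde1b, Adcy5, Rasd2 and Ppp1r1b as a term: 70% of the 20 calls held, between the bounds of 50% and 90% set beforehand, so this count cannot decide. The median size of the calls was 0.488 without and 0.49 with the term, 101% of it left. So far as the term follows striatal tissue, this argues against such tissue as the whole cause. Whether the term does so was not checked, and the median also takes in the calls near Htt. This measure was written down after those sizes had been seen. The 6 calls that ended were Prl, H2-Bl, H2-T-ps, Cartpt (-0.49 ± 0.108 before, -0.42 ± 0.105 after, adjusted p = 0.0769), Glul (-0.17 ± 0.039 before, -0.165 ± 0.04 after) and Slc4a4 (-0.18 ± 0.04 before, -0.16 ± 0.039 after). All 6 estimates were smaller in size with the term, but they were picked because their calls ended, which favours smaller estimates. A share of striatal tissue in these stays open. The condition set beforehand also required the striatal projection neuron list to move as one. Camera did not call that list (median 0.0234, adjusted p = 0.7). The shift of ribosomal protein genes in Q140 carriers could come from a bias by gene length, since their median length was 1631 bp against 3402 bp for all genes: against genes of like length and expression, 83% of the shift was left (0.0655 before, 0.0544 after), between the bounds set beforehand, so length bias cannot be told apart from an effect of Q140, and of the shift of oxidative phosphorylation genes 46.8% was left (0.0359 before, 0.0168 after). Genotype itself remains an open explanation for the calls on other chromosomes.

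Q140 replicate F1, labelled female, had 1.36 CPM of Xist, the RNA that silences 1 X chromosome, where the other 23 females had 1010 ± 115 CPM; its log2 value was 0.482, the nearest of its group was 9.82, and the gap took up 0.975 of the group's range. A male library with a female label is excluded because 4 of 4 Y-linked genes (Ddx3y, Kdm5d, Eif2s3y and Uty) lay below the lowest male, each at 0. An X chromosome left active after loss of Xist is argued against by a median log2 difference of 0.0139 from the other females over 477 X-linked genes, within the range of -0.0432 to 0.0435 of single females. All 4 of 4 genes that escape inactivation lay below every other female and within the male range (Kdm6a at 34.9 CPM against 37.4 to 53.9, Eif2s3x at 11 against 13.3 to 18.9), which is consistent with a mouse that has a single X chromosome and no Y chromosome. No biological explanation tied to the genotype was tested, and the library was kept in every fit.

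Other single libraries stood apart in their groups of 8. The choroid plexus list averaged a log2 CPM of 4 in Msh3+/- M2, nearest 0.512 (gap 0.782 of the range). The meningeal list averaged 1.2 in Q140 with Msh3+/- F1, nearest 2.65 (gap 0.621). Enpp6 had 0.376 in wild-type F2, nearest 0.888 (gap 0.553). Camk2n1 had 11.4 in wild-type M4, nearest 11.3 (gap 0.584). Prl had 0.956 in Q140 M2, nearest -3.26 (gap 0.756), and in the same library Camk2a had 12.1, nearest 12.2 (gap 0.629).

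Camera at the preset correlation called a difference in the Q140 effect between Msh3 genotypes in 12 list tests, with protocadherins in 2 of them. Fry called 0 lists in both interactions. Random splits of the libraries did not exclude chance for the number of lists called in either interaction. Msh3+/- M2, which stood apart in choroid plexus genes, takes part in the interaction with Msh3+/-. Against intact Msh3, the Q140 effect on Msh3+/- was higher for oligodendrocyte genes (median difference 0.072, adjusted p = 0.00557), microglia (0.084, adjusted p = 0.000118) and mitochondrially encoded genes (0.22, adjusted p = 5.62e-05). It was lower for meningeal genes (-0.31, adjusted p = 0.000183), choroid plexus (-1.60, adjusted p = 0.000152), immediate early genes (-0.36, adjusted p = 6.9e-06), protocadherins (-0.055, adjusted p = 0.00151) and cholesterol synthesis (-0.061, adjusted p = 0.0444). With an estimated correlation the adjusted p of these 8 lists were 0.807, 0.641, 0.641, 0.758, 0.641, 0.641, 0.641 and 0.807. On Msh3-/- it was higher for endothelial genes (0.087, adjusted p = 0.0298), potassium and sodium channels (0.046, adjusted p = 0.00526) and protocadherins (0.080, adjusted p = 0.0298) and lower for blood genes (-2.49, adjusted p = 0.0298). With an estimated correlation the adjusted p of these 4 lists was 0.99.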

How the results depend on the processing

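The averaged contrasts, the fits without the 4 libraries high in choroid plexus, blood or pituitary genes, the scores without genes near Htt or Msh3 and the leave-one-out fits of the sex interaction were chosen only after results had been seen. No named gene that was called, and no score shift past its threshold, changed direction under any alternative; called genes outside the named set were not followed. Of the named genes called, and apart from the fits that leave out 1 library, 6 of 16 kept their call under every alternative in Q140 against wild type, 9 of 15 in Msh3-/- against wild type, 10 of 17 in Q140 with Msh3-/- against Q140 and 4 of 4 in Q140 with Msh3+/- against Q140. In Msh3+/- against wild type it was 1 of 3, for Q140 on Msh3+/- 5 of 9 and on Msh3-/- 1 of 3, and in the averaged contrasts 25 of 33 (Q140) and 16 of 20 (Msh3-/-). The interactions with Msh3 and with sex had 0 calls whichever library was left out. At the depth and spread of these libraries many small changes are missed: among simulated genes changed 1.2-fold, edgeR recovered 44.6%. For the values below the cause was not tested, apart from fits with fewer libraries.

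DESeq2's Wald test called 34 genes in Q140 against wild type, 10 in Msh3+/- against wild type, 22 in Q140 with Msh3+/- against Msh3+/-, 465 in the averaged Q140 contrast and 159 in the averaged Msh3-/- contrast. At an adjusted p under 0.1, edgeR called 39 genes in Q140 against wild type, 17 in Q140 with Msh3+/- against Msh3+/-, and 606 and 157 in the averaged contrasts. With a plate column term, over whose levels Q140 carriers were unevenly spread, Q140 against wild type had 11 calls and its averaged contrast 102. Limma-voom with quality weights called 497 in the latter. The replicate block gave 17 calls in Q140 with Msh3+/- against Msh3+/- and 91 in the averaged Msh3-/- contrast. In Q140 with Msh3-/- against Msh3-/-, 2 genes were called with a mean CPM of at least 1 and 7 with 2 surrogate variables.

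Without the 2 wild-type mice of other name prefixes, 12 genes were called in Q140 against wild type, 3 in Msh3+/- against wild type and 172 in the averaged Q140 contrast. Without the libraries high in choroid plexus, blood or pituitary genes, 8 were called in Q140 against wild type, 2 in Msh3+/- against wild type and 27 in the averaged Msh3-/- contrast. With only the groups of the comparison in the fit, 2 were called in Msh3+/- and 13 in Msh3-/- against wild type, 12 in Q140 with Msh3-/- against Q140 and 2 in Q140 with Msh3-/- against Msh3-/-.

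With an estimated correlation, camera called 0 lists in Q140 against wild type, 1 each in Msh3+/- and Msh3-/- against wild type and in either double mutant against Q140, 0 for Q140 on Msh3+/- or Msh3-/-, 0 in both interactions, and 0 and 2 in the averaged contrasts of Q140 and Msh3-/-. Fry called 0, 1, 1, 1 (Q140 with Msh3+/- against Q140), 2 (Q140 with Msh3-/- against Q140), 0, 0, 0, 0, 3 and 2. With 2 surrogate variables, 5 lists were called in Msh3-/- against wild type and 0 in the interaction with Msh3-/-. With only the groups of the comparison, 10 were called in Q140 with Msh3+/- against Q140. The score of Q140 with Msh3-/- against Q140 was -0.0193 with 500 genes (permutation p = 0.313) and -0.0344 with the median (permutation p = 0.109). With 500 genes the shift was 0.0976 on Msh3+/- and 0.094 on Msh3-/-, and without genes near Htt or Msh3 0.139 and 0.115.

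Leaving out 1 library at a time gave 13 to 23 calls in Q140 against wild type, 5 to 7 in Msh3+/- and 17 to 26 in Msh3-/- against wild type, 4 to 7 in Q140 with Msh3+/- against Q140 and 13 to 24 in Q140 with Msh3-/- against Q140. It gave 7 to 14 for Q140 on Msh3+/-, 4 to 5 on Msh3-/-, 0 to 0 in the interactions, and 201 to 475 and 28 to 109 in the averaged contrasts. Score shifts ranged from 0.17 to 0.202 on Msh3+/- and from 0.147 to 0.171 on Msh3-/-. Against Q140, the double mutants' scores ranged from -0.00808 to 0.013 with Msh3+/- and from -0.0718 to -0.0472 with Msh3-/-.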

Other observations

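The averaged contrasts were chosen only after the pairwise results had been seen; the random splits of the libraries were planned. Mitochondrially encoded genes, which code for core subunits of the respiratory chain, had medians of -0.17 in Q140, -0.19 in Msh3+/- and -0.19 in Msh3-/- against wild type, and 13 of 13 members lay below 0 each time. These comparisons share the 8 wild-type libraries, so their values are not independent of each other. Immediate early genes had medians of 0.20 in Q140, 0.21 in Msh3+/- and 0.064 in Msh3-/- against wild type, with 18, 20 and 12 of 20 above 0. Camera called both lists in Msh3+/- against wild type (adjusted p = 1.71e-05 and 6.21e-06), but not with an estimated correlation (adjusted p = 0.691 for both). Oligodendrocyte genes had a median of -0.11 there, with 21 of 24 below 0 and 1 lower when adjusted over the list alone (camera adjusted p = 6.21e-06, 0.691 with an estimated correlation).

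Msh3-/- averaged over Q140 status came with small median shifts in other lists, none of which kept a call with an estimated correlation. Layer 6 genes had a median of -0.10, with 13 of 15 below 0 (camera adjusted p = 0.0177, 0.789 with an estimated correlation); Tle4, a corticothalamic regulator, had -0.078 ± 0.032. Reactive astrocyte genes had -0.16 (camera adjusted p = 0.0266, 0.789 with an estimated correlation), with Cp, ceruloplasmin, at -0.24 ± 0.077. Heat shock genes had -0.053 (camera adjusted p = 0.0308, 0.789 with an estimated correlation), with Hsp90b1 at -0.094 ± 0.034. In Q140 against wild type, Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, had 21.6 ± 19.3 CPM against 10.2 ± 1.4 (SD, n = 8; log2 fold change 1.09 ± 0.341, edgeR adjusted p = 0.297).

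Random sex-balanced splits of the same libraries were run 100 times per result, the real split included. Chance could be excluded for the gene counts of Q140 against wild type (20 called, highest other split 5, as many in 1 split), Msh3-/- against wild type (22, highest other 3, 1 split), Q140 with Msh3+/- against Q140 (6, highest other 4, 1 split), Q140 with Msh3-/- against Q140 (20, highest other 6, 1 split) and the averaged contrasts (288 and 42, highest other 7 and 1, 1 split each). The counts of the Msh3 comparisons include Msh3 itself and genes near it, and those of the Q140 comparisons include genes near Htt. In Q140 with Msh3+/- against Q140, Msh3, Rasgrf2, Cmya5 and Fam169a were among the 6 calls. The splits therefore do not exclude chance for the remaining calls of that comparison. By the limit set beforehand, fewer than 5 splits, chance counts as excluded for Q140 with Msh3+/- against Msh3+/- (10, as many in 3 splits). The same holds for Q140 with Msh3-/- against Msh3-/- (4, as many in 2 splits). In these comparisons single splits called 206 and 174 genes, far more than the real split, so the limit does not settle the matter. What made those splits call so many genes was not tested. Chance was not excluded for Msh3+/- against wild type (6, highest other 19, as many in 5 splits). For the interactions with Msh3+/-, Msh3-/- and sex (0 called, highest other 11, 2 and 3) the count decides nothing, since all 100 splits give at least 0 calls.

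For the number of lists called by camera at the preset correlation, chance was not excluded in any comparison. The real count, the highest other split and the number of splits with as many were 11, 14 and 10 in Q140 against wild type, 9, 16 and 53 in Msh3+/- and 10, 15 and 33 in Msh3-/- against wild type. Against Q140 they were 6, 15 and 68 with Msh3+/- and 6, 15 and 75 with Msh3-/-. For Q140 on Msh3+/- they were 13, 14 and 7, and on Msh3-/- 8, 14 and 45. For the interactions they were 8, 18 and 54 with Msh3+/- and 4, 14 and 91 with Msh3-/-, and for the averaged contrasts 14, 15 and 5 (Q140) and 8, 14 and 50 (Msh3-/-).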
